A study of Homo sapiens with 7 samples.

How the data were processed

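The study treated BJAB, a human B cell lymphoma line, for 9 h with DMSO or with 2 or 10 µM of BNTX, naloxone or naltrindole, and measured RNA on Illumina bead arrays. Per the labels' protocols, the cells grew in medium with 10% FCS, samples with an RNA integrity number above 9 were used, and 500 ng of RNA per sample was amplified into biotin-labelled cRNA. There were 7 arrays, 1 per treatment, so no treatment was replicated and the number of arrays limits the precision of every value.

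The deposited table held, per the file headers, an intensity and a detection p-value for each of 47313 probes on each array. The deposited intensity values were on a linear scale, not normalized between arrays and without background subtraction (lowest values 80 to 85.4). The deposited p-value of each probe states how often negative control probes were as bright. The scanner software was not given in the sources used here. The authors' processed values were on the log2 scale, and their medians lay between 6.684 and 6.685 on the 7 arrays. Set against the intensities of the same arrays they had a rank correlation of 1, and they differed by at most 0.0477 from a quantile normalization of the log2 intensities made here. The scale, centring and direction of these values were thus known, with no background subtraction visible, and they served as an alternative. The submitters' processing notes name limma, with no version or role.

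Probes were named through the platform annotation: 30107 probes had 1 symbol, 8 had several and 17198 had none. Probes of the last 2 kinds were named after no gene. Gene identifiers of 30068 probes matched a RefSeq gene table, which changed 0 symbols. No genome build was given in the sources used here, so no coordinates are printed.

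Values were computed with R 4.3.3 and limma 3.58.1. The main setting was limma's neqc: background correction by normexp, with the negative controls inferred from the detection p-values, an offset of 16, quantile normalization and log2. A probe counted as above background on an array at a detection p-value below 0.01. Each gene was represented by its brightest probe among those with 1 symbol that were above background on at least 1 array, which gave 10506 genes, of which 2721 had several such probes. Where a gene was not above background on 1 of 2 arrays compared, its fold is a bound, written as "at least", and was computed against the higher of the probe's own signal and the lowest signal of any probe above background on that array.

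With 1 array per treatment, differences between arrays have no replicate check and no p-value. They were counted by a rule of size, a difference of 1 or more on the log2 scale (2-fold). This was done for each treated array against DMSO, for the compounds at matched dose and for 10 µM against 2 µM of each compound. A limma fit with 1 mean per compound (the compound fit) used the 2 doses of a compound in place of replicates. Its spread therefore holds the dose effect as well as the noise of the arrays (3 residual degrees of freedom, 5.82 prior degrees of freedom). The lone DMSO array was assumed to vary like the others. A further limma fit on the 6 treated arrays tested whether the dose difference of BNTX differed from the mean dose difference of naloxone and naltrindole (the dose interaction). It had 1 residual degree of freedom, the dose difference of naloxone against that of naltrindole, and its spread came from the trend of the variance with brightness. With 1 BNTX array per dose, no spread between BNTX arrays enters its standard errors and p-values. Both fits used eBayes with a trend, two-sided moderated tests and Benjamini-Hochberg adjustment over genes at 0.05. Values with ± are log2 differences and standard errors of these fits. In the results, differences of genes and lists given without the word fold are on the log2 scale. Nothing in the labels says that the arrays came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

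There were 25 gene lists, covering stress responses, protein quality control, B cell and plasma cell genes, signalling, cell cycle, metabolism, opioid receptors and peptides, reference genes and markers of other cell types. Each list has its median difference on an array and the percentile of that median among 10000 random lists of the same size matched on expression in 10 bins, as a description of these arrays. Lists with 3 or more measured members (24 of 25) were tested between compounds with limma's camera, at a preset inter-gene correlation of 0.01 and again with an estimated one, adjusted over the lists. The lists, the tests and the alternatives were fixed before the data were examined, apart from those named as chosen later.

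The genes named were set by rule. They are the 15 highest and 15 lowest in BNTX 10 µM minus DMSO with the same sign against naloxone and naltrindole at 10 µM and in BNTX 2 µM minus DMSO, and likewise the 5 highest and 5 lowest at 2 µM. They also include the 4 highest and 4 lowest for naloxone and for naltrindole by the smaller difference of both doses, the 5 with the largest BNTX dose difference, up to 4 members of each list with the largest BNTX difference from the other antagonists, and the opioid receptor and peptide genes. This gave 135 genes.

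The pipeline was tested on simulated arrays with the noise of the naltrindole arrays and 200 changed genes in BNTX. Changes of 2-fold at both doses were recovered at 99% by the compound fit, with 9 other calls, at 52.5% by the 2-fold rule and at 0% by the dose interaction. Changes of 4-fold that were present only at 10 µM were recovered at 0% by the compound fit, at 99.5% by the dose interaction and at 100% by the 2-fold rule. Changes of 4-fold at 10 µM with a smaller change at 2 µM were recovered at 0%, 92% and 100%. With no change, the fits called 0 genes and the 2-fold rule called 3 of 10506. The simulated noise was normal and of the same size on all arrays for genes of like brightness. It came from a quiet pair, with an SD of the log2 dose difference of 0.205 for naltrindole against 0.422 for naloxone. These rates may thus not hold for the measured arrays.

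The alternatives were quantile normalization without background correction, median centring in place of quantile normalization, the authors' processed values, an offset of 50, other filters on dim probes, the mean of a gene's probes and other size rules. Median centring set the median of all 47313 probes equal on every array. Most of these probes were not above background, so the medians of the 10506 genes could still differ between arrays. For BNTX against DMSO, the mean of naloxone and naltrindole also served as the reference. For the fits they were dose as a block, the 6 treated arrays, a slope on dose, other variance models and leaving out each array in turn. For the lists they were an estimated correlation and leaving out genes that another list also holds.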

Results

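Transcript levels were measured in BJAB cells, a human B cell lymphoma line, after 9 h with DMSO or with 2 or 10 µM of BNTX, naloxone or naltrindole. All 3 are opioid receptor antagonists with a morphinan skeleton. BNTX is 7-benzylidenenaltrexone, naltrindole carries an indole fused to that skeleton, and naloxone bears an N-allyl group. The series title places the study in the field of immunosuppression of B cells by BNTX, and the comparisons ask which transcripts differ with BNTX and whether they also differ with the other antagonists at the same dose. Each treatment had 1 array and there were no replicates. The mean intensity of the 47313 probes ranged from 292 (BNTX 2 µM) to 360.4 (naloxone 10 µM), and 31.2% (BNTX 10 µM) to 33.4% (naloxone 10 µM) of probes were above background.

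In cells treated with BNTX at 10 µM, transcripts of heat shock and other stress proteins were higher than in DMSO. HMOX1, which encodes the heme-degrading enzyme heme oxygenase, was 51.9-fold higher. The inducible heat shock genes HSPA6, DNAJB1 and HSPA4L were 24.3-fold, 10.6-fold and 8.2-fold higher. The second probe of HSPA6 stood at a log2 difference of 2.81, against 4.60 for its brightest probe. HSPA7 was 11.3-fold higher and the co-chaperone gene BAG3 8.73-fold. DDIT3, a transcription factor gene of the integrated stress response, was 15.8-fold higher. BHLHE40, a transcriptional repressor gene, was 13.8-fold higher, ZFAND2A 11.7-fold, the lysosomal carboxypeptidase gene CTSA 10.6-fold and the lymphocyte surface receptor gene LY9 9.37-fold. PLCH2, CEMIP and RMRP were not above background in DMSO and were at least 18.7-fold, 13.4-fold and 8.35-fold higher. The 5S ribosomal RNA gene RNA5S9 was 13.5-fold higher.

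Other transcripts were lower with BNTX at 10 µM. DDN was 5.29-fold lower than in DMSO, the pseudouridine synthase gene PUS7 4.71-fold, RRP12 4.54-fold, the tRNA methyltransferase gene METTL1 4.47-fold, RRS1 4.32-fold and NOP16 4.17-fold. The kisspeptin receptor gene KISS1R was 4.14-fold lower, the small nucleolar RNA SNORA24 3.95-fold and DLEU1 3.74-fold. HMGCS1, an enzyme gene of sterol synthesis, was 3.89-fold lower, and HSPA5, the main chaperone gene of the endoplasmic reticulum, 3.71-fold. SCO2, GTPBP3 and PSMG4 were 3.69-fold, 3.65-fold and 3.64-fold lower. TLCD1 was not above background with BNTX at 10 µM and was at least 2.9-fold lower. By the 2-fold rule, 420 genes were higher and 377 lower with BNTX at 10 µM than in DMSO, of 10506. The counts were 178 and 109 in the authors' processed values.

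**Figure D1:**
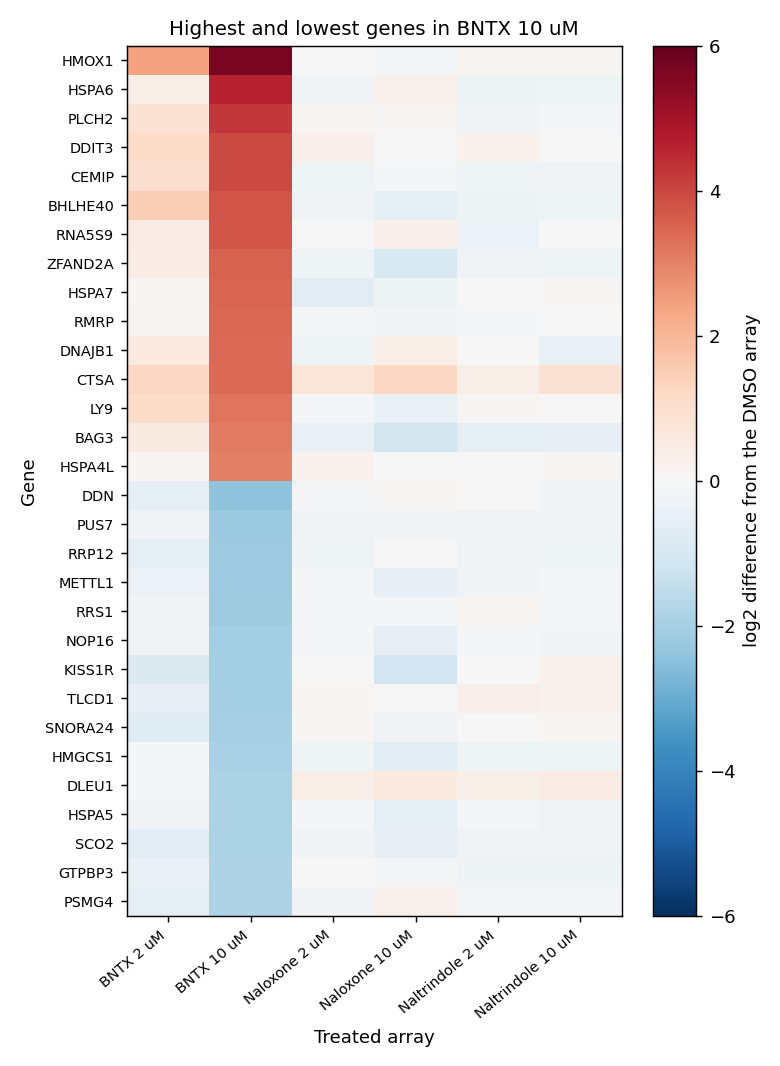
Heat map of the log2 difference from the DMSO array for the 15 highest and 15 lowest named genes of BNTX 10 µM (vertical axis), on each of the 6 treated arrays (horizontal axis), with a colour scale from lower (blue) to higher (red). The colours show measured values, which are no exact sizes for PLCH2, CEMIP, RMRP, HSPA7 and TLCD1 where an array did not have them above background. HMOX1 differed by 2.40 at 2 µM and by 5.70 at 10 µM of BNTX, and by -0.08 and 0.05 with naloxone and naltrindole at 10 µM.

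The stress lists were higher as groups with BNTX at 10 µM. Of 23 measured heat shock genes, 17 were at least 2-fold higher than in DMSO and 0 were 2-fold lower, with a median difference of 1.55. Of 21 measured targets of NRF2, the regulator of antioxidant genes, 7 were 2-fold higher and 1 lower (median 0.55). GCLM and TXNRD1, of glutathione synthesis and thioredoxin reduction, were 2.41-fold and 2.03-fold higher, with log2 differences of 0.46 and 1.01 for their second probes. Of 25 measured genes of the ATF4 and amino acid response, 7 were 2-fold higher and 0 lower (median 0.45), with PPP1R15A 5.41-fold and ATF3 2.61-fold higher. Of 6 measured metallothionein and metal response genes, 3 were 2-fold higher (median 1.03), among them the zinc exporter gene SLC30A1 at 2.8-fold. Each of these medians lay at or above percentile 99.99 of matched random lists. The immediate early list went both ways, with 4 of 15 members 2-fold higher and 4 lower (median 0.43, percentile 99.8). Its member DUSP1, a phosphatase gene of MAP kinase signalling, was 4.43-fold higher.

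Mitotic genes were also higher with BNTX at 10 µM, and chaperone genes of the endoplasmic reticulum and genes of sterol synthesis were lower. Of 23 mitosis genes, 7 were 2-fold higher and 0 lower (median 0.71, percentile 100). AURKA, a spindle kinase gene, was 2.93-fold higher and the kinetochore genes CENPE and CENPF 2.98-fold and 2.74-fold. The DNA replication list had a median of -0.03 (percentile 54.8), with 0 of 19 members 2-fold higher and 2 lower. Of 17 measured chaperone genes of the endoplasmic reticulum, 5 were 2-fold lower and 0 higher (median -0.72, percentile 0). Of 18 measured cholesterol biosynthesis genes, 6 were 2-fold lower and 1 higher (median -0.83, percentile 0). DHCR7 and NSDHL were 2.97-fold and 2.78-fold lower, and SC5D was 2.03-fold higher.

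Among the lists of immune function, 26 NF-kB targets were measured with BNTX at 10 µM, of which 6 were 2-fold lower than in DMSO and 2 higher (median -0.27, percentile 1.41). The chemokine receptor gene CCR7 was 3.35-fold higher, the NF-kB inhibitor gene TNFAIP3 2.65-fold higher and NFKB2 2.48-fold lower. Of 9 plasma cell genes 2 were 2-fold lower (median -0.40, percentile 2.5), namely FKBP11 at 2.73-fold and XBP1 at 2.08-fold, and the median was -0.56 against naloxone and -0.85 against naltrindole at 10 µM (percentiles 1.17 and 0). Of 9 MHC class II genes 1 was 2-fold lower (median -0.18, percentile 18.3), namely CIITA, the transactivator of the class, at 3.27-fold. The list of B cell identity and B cell receptor signalling had 1 of 26 members 2-fold lower, SPIB at 2.91-fold, and a median of 0.07 that became -0.00 (-0.0026) with median centring. The Toll-like receptor list had 1 of 14 members 2-fold lower, UNC93B1 at 2.03-fold (median 0.01, percentile 53.9). The second probe of UNC93B1 stood at a log2 difference of -0.33. In the type I interferon list, 1 of 10 members was 2-fold higher and 1 lower (median -0.11, percentile 30.5). OAS1 was the higher one, by 2.80, and its 4 probes ranged from 0.19 to 3.01.

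The remaining lists with BNTX at 10 µM were as follows. Glycolysis and hypoxia genes had a median of -0.34 (percentile 1.27), with 1 of 17 2-fold higher, VEGFA at 2.02-fold. The proteasome list had a median of 0.24 (percentile 99.97) with 0 of 27 past 2-fold. The apoptosis list of the BCL2 family had 2 of 15 2-fold higher (median -0.17, percentile 16.2). The survival gene BCL2 was 4.21-fold higher. The pro-apoptotic gene HRK, not above background in DMSO, was at least 5.85-fold higher. Of 14 measured p53 targets 1 was 2-fold higher, TP53INP1 at 3.23-fold, and 1 lower (median -0.08, percentile 33.1). Cytosolic ribosomal protein genes had a median of -0.08 (percentile 35.1) and reference genes 0.02 (percentile 67.6), with 0 members of either past 2-fold. Markers of other cell types were mostly below background. Of the myeloid markers 4 of 12 were measured (median 0.22, percentile 80.5) and CD14 was 2.57-fold higher. Of the epithelial and fibroblast markers 3 of 12 were measured (median 0.02, percentile 55.6). Of the T cell markers 2 of 12 were measured, CD3G at -0.08, while CD28 was above background on neither array of this comparison.

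**Figure D2:**
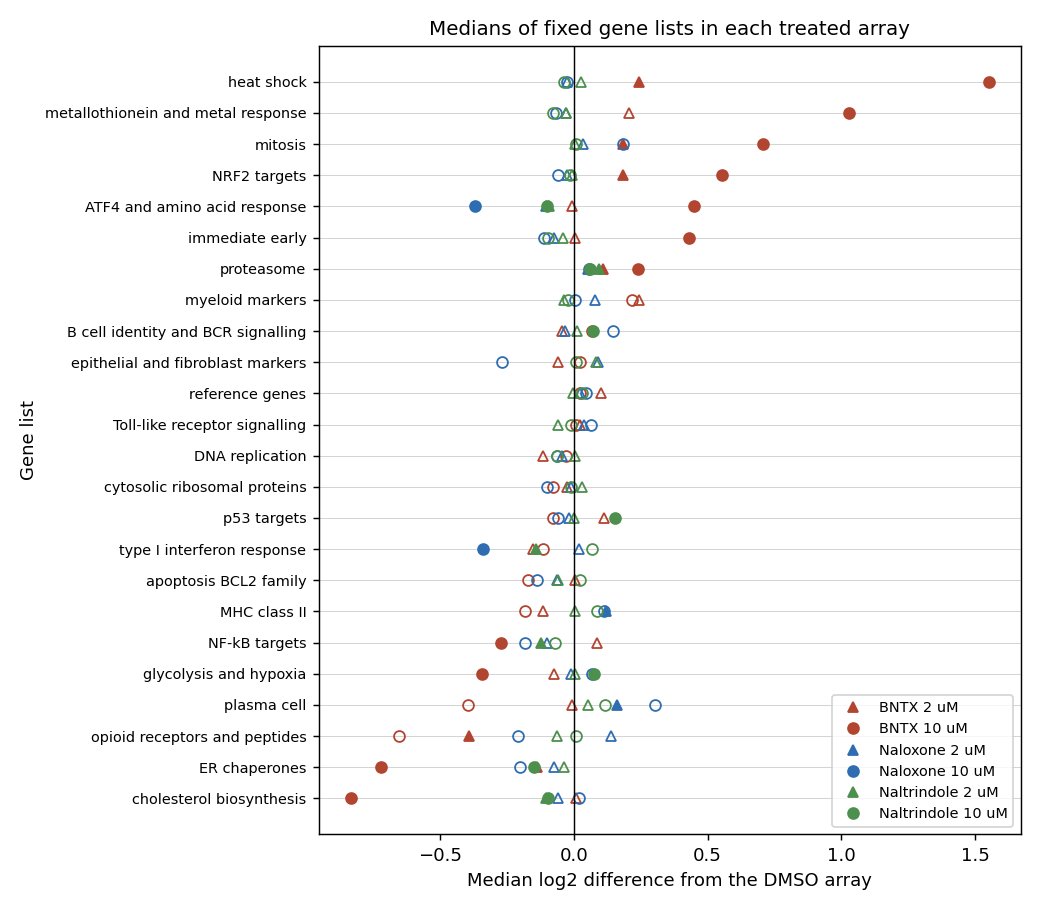
Median log2 difference from the DMSO array (horizontal axis) of each fixed gene list with 3 or more measured members (vertical axis), on the 6 treated arrays. Triangles mark 2 µM and circles 10 µM, colours mark the compound, and filled symbols mark medians in the outermost 5% of matched random lists, both ends together. The heat shock list stood at 1.55 and the cholesterol biosynthesis list at -0.83 with BNTX at 10 µM.

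Opioid receptor genes were mostly not detected in these cells. OPRM1, OPRD1 and OPRK1, the genes of the mu, delta and kappa receptors, were not above background on any of the 7 arrays, nor were the peptide genes PDYN and POMC, and PENK was not analysed here. OPRL1, the nociceptin receptor gene, differed from DMSO by -1.32 with BNTX at 10 µM, and its second probe by -0.27. The growth factor receptor gene OGFR differed by -0.65 and the nociceptin precursor gene PNOC by 0.14. The list of these 3 measured genes had a median of -0.65 (percentile 4.88).

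At 2 µM of BNTX, 21 genes were 2-fold higher and 6 lower than in DMSO. HMOX1 was 5.28-fold higher, CCR7 3.53-fold, BCL2 3.05-fold, HAVCR2, an inhibitory receptor gene, 3-fold and BHLHE40 2.83-fold. GMPPB was 2.61-fold lower, with a log2 difference of -0.24 for its second probe. LRRC45 was at least 2.03-fold lower, and another of its probes stood at -0.14 on the log2 scale. RPTOR and AEBP1 were at least 1.73-fold and 1.33-fold lower, and CIITA was 1.94-fold lower. The medians of the heat shock, NRF2 and mitosis lists were 0.24, 0.18 and 0.18 (percentiles 100, 99.7 and 99.7), and those of the ATF4 and cholesterol biosynthesis lists were -0.01 and 0.01 (percentiles 54 and 59.5), the last turning to -0.03 with median centring. Without background correction 2 genes were 2-fold higher and 0 lower.

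Naltrindole differed little from DMSO by the 2-fold rule, with 4 genes higher and 4 lower at 2 µM and 2 higher and 3 lower at 10 µM. Naloxone at 2 µM had 5 higher and 2 lower. Median centring gave splits of 1 and 2, 3 and 1, and 6 and 1 for these comparisons, and quantile normalization without background correction gave 0 genes. The genes named as higher at both doses of naloxone were CTSZ, a lysosomal cathepsin gene (1.51 at 2 µM and 1.85 at 10 µM), IPO7 (1.12 and 0.95), PPP3R1 (1.10 and 1.18) and LRRC72, which was not above background in DMSO (at least 1.38-fold and 1.45-fold). CTSZ also stood at 0.83 and 1.41 with naltrindole, PPP3R1 at 0.93 and 0.98 and ANP32AP1 at 0.66 and 0.86. PCOLCE, not above background in DMSO, was at least 1.34-fold and 1.27-fold higher with naltrindole. PTPRC, the gene of the leukocyte antigen CD45, stood at -1.32 with naloxone at 10 µM and at -1.08 with naltrindole at 2 µM. It was not above background with naloxone at 2 µM and naltrindole at 10 µM, where it was at least 2.48-fold and 2.34-fold lower than in DMSO. TGFBRAP1 stood at -0.82 and -1.15 with naloxone. AGAP2-AS1 and OR5AN1 with naloxone and IL9R, CREB3L2-AS1 and SLC35D4 with naltrindole were not above background at either dose. At 2 and 10 µM they were at least 1.89-fold and 1.94-fold (AGAP2-AS1), 1.22-fold and 1.25-fold (OR5AN1), 1.18-fold and 1.12-fold (IL9R), 1.21-fold and 1.15-fold (CREB3L2-AS1), and 1.66-fold and 1.58-fold lower (SLC35D4). The 2 probes of CREB3L2-AS1 differed in sign with BNTX at 2 µM, where its brightest probe was not above background. Of these 13 genes, 11 had the same sign on all 6 treated arrays by their measured values, background included. In simulated arrays without any effect, set against a shared control, this held for 14 of 16 genes chosen by the same rule. Across genes, the differences from DMSO of naltrindole at 2 and 10 µM correlated at r = 0.56 (0.49 simulated, with covariances of 0.0269 and 0.0199). This was not particular to the doses of naltrindole, since naloxone at 2 µM correlated with naltrindole at r = 0.57 (2 µM, covariance 0.0282) and r = 0.60 (10 µM, covariance 0.0291). Part of the excess may come from the single DMSO array they share, and genes are not independent replicates.

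Naloxone at 10 µM stood apart from the other arrays of naloxone and naltrindole, with 121 genes 2-fold higher and 271 lower than in DMSO. It was also the brightest array. Median centring over all probes left a median of all genes of 0.34 in this comparison and gave 668 higher and 54 lower, so no direction is read from the split. CDT1, a replication licensing gene, and IRF1, an interferon regulatory factor gene, stood at -1.67 and -1.40, and SPIB at 1.15. The median of the ATF4 list was -0.37 (percentile 0.15) and was -0.04 with median centring, -0.38 relative to that median of all genes. Across genes with several probes, the brightest and the second probe of a gene correlated at r = 0.126 in the difference between naloxone and naltrindole at 10 µM, against 0.745 for BNTX and naltrindole at 10 µM. Between arrays with few differences it was 0.0931 (naltrindole at 10 and 2 µM) and 0.0763 (naloxone and naltrindole at 2 µM). In a test chosen after the data were seen, 85 genes 2-fold apart between naloxone and naltrindole at 10 µM had a second probe. That probe had the same direction in 43 of them (50.6%), against 193 of 208 (92.8%) for BNTX and naltrindole. Values of single genes on the naloxone 10 µM array carry that limit.

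At matched dose, BNTX differed from both other antagonists by more genes than these differed from each other. At 10 µM, 719 genes were 2-fold higher and 606 lower with BNTX than with naloxone, 412 higher and 359 lower than with naltrindole, and 200 were higher and 104 lower with naltrindole than with naloxone. HMOX1 was higher with BNTX by 5.78 and 5.65 on the log2 scale than with naloxone and naltrindole, and HSPA6 by 4.35 and 4.87. The heat shock list had a median of 1.73 against naloxone and 1.59 against naltrindole, and the cholesterol biosynthesis list -0.87 and -0.76. At 2 µM, 22 genes were higher and 12 lower with BNTX than with naloxone, 23 higher and 7 lower than with naltrindole, and 4 higher and 0 lower with naltrindole than with naloxone. Median centring over all probes left medians of all genes of -0.31 (BNTX minus naloxone) and -0.27 (naltrindole minus naloxone) at 10 µM and of -0.11 (BNTX minus naloxone) at 2 µM. It turned those splits to 321 and 1504, 60 and 432, and 13 and 17. For BNTX minus naltrindole at 10 µM it gave 361 higher and 435 lower, so which direction held more genes depended on the scaling. Quantile normalization without background correction gave 171 and 93 for BNTX minus naltrindole at 10 µM, and at 2 µM 3 and 0 against naloxone and 2 and 0 against naltrindole.

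**Figure D3:**
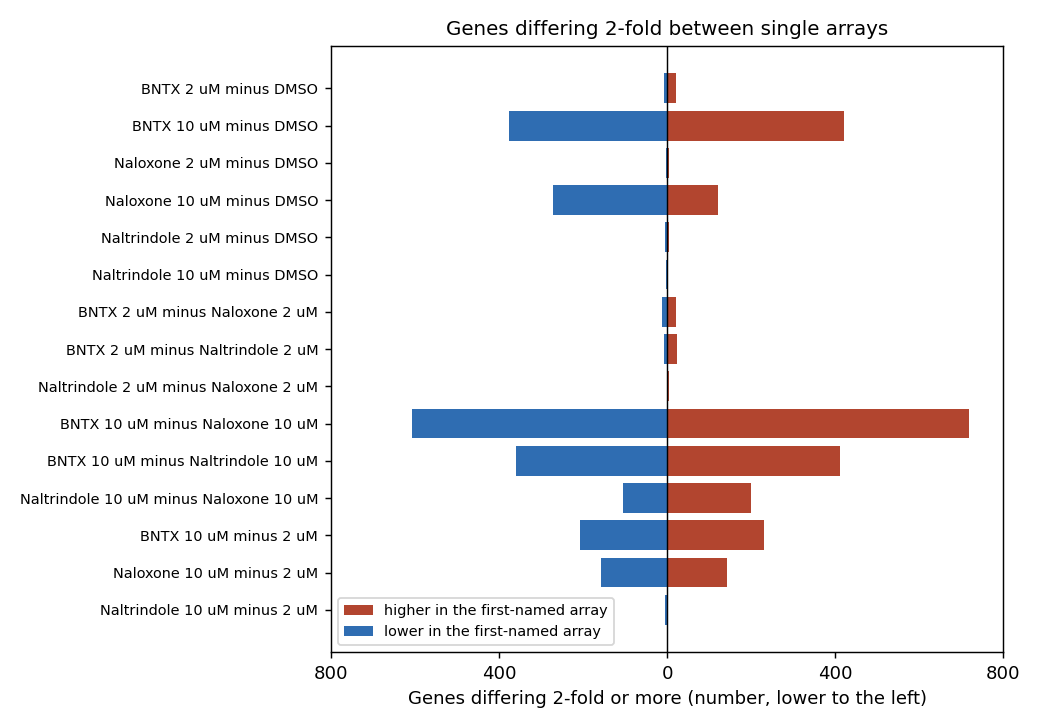
Number of genes differing by 2-fold or more between 2 single arrays (horizontal axis, lower to the left and higher to the right of 0) for each comparison (vertical axis). With BNTX at 10 µM 420 genes were higher and 377 lower than in DMSO. The 121 higher and 271 lower genes of naloxone at 10 µM became 668 and 54 with median centring.

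Over both doses, 3 genes rose with BNTX relative to the mean of naloxone and naltrindole in the compound fit. These were CCR7, a chemokine receptor gene of lymphocyte homing (2.24 ± 0.20, adjusted p = 0.0166), BCL2 (1.92 ± 0.19, adjusted p = 0.017) and HAVCR2 (1.55 ± 0.18, adjusted p = 0.049) in limma's moderated test, each higher in both BNTX arrays than in all 4 others. Against naloxone alone 1 gene rose, CCR7 (2.44 ± 0.23, limma adjusted p = 0.0269). Against naltrindole alone limma called 0 genes, with 1095 at an unadjusted p below 0.05, and the smallest adjusted p was 0.0585 (BCL2 and CCR7). With dose as a block limma called these 2 genes against naltrindole (adjusted p = 0.049 for each) and against naloxone, and 11 genes against both. With median centring it called CCR7 against naltrindole (limma adjusted p = 0.0285). HAVCR2 was no longer called against both with median centring, without a variance trend, with a robust variance model or without a detection filter (limma adjusted p = 0.0606, 0.0653, 0.0571 and 0.258, in a range of 0.00024 to 0.355 over all alternatives). BCL2 was lost without a detection filter (limma adjusted p = 0.0872). Between naltrindole and naloxone limma called 0 genes, with 124 at an unadjusted p below 0.05. The median 95% interval of that difference extended 0.51 to either side, so differences of such a size between these compounds are not excluded. Against DMSO limma called 0 genes for BNTX, naloxone and naltrindole, with 644, 179 and 87 at an unadjusted p below 0.05. The counts rested on single arrays: without BNTX 2 µM they were 1320 against both, 1019 against naloxone, 833 against naltrindole and 396 against DMSO. Against both, 1 gene was called without BNTX 10 µM, HMOX1 and none of the 3 above (limma adjusted p = 0.0341), and 1 without naloxone 2 µM, CCR7. Without naloxone 10 µM, naltrindole 2 µM or naltrindole 10 µM limma called 0 genes against both, with 1466, 929 and 912 at an unadjusted p below 0.05. With any 1 of these 5 arrays left out, 0 genes were called against naloxone alone. A slope on dose in place of 1 mean per compound called 2931 genes for BNTX against both, 3135 against naloxone, 1944 against naltrindole, 391 between naltrindole and naloxone, 2261 for BNTX against DMSO and 1326 for naloxone against DMSO. Such a slope gives each 10 µM array more weight than the 2 µM array of that compound. The counts that involve naloxone thus lean on the naloxone 10 µM array and carry the limit given for it above.

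Of the 24 lists tested between BNTX and both other antagonists, 9 passed in camera at the preset correlation. The heat shock (median 1.01, adjusted p = 2.61e-09), mitosis (0.48, 4.05e-06), ATF4 (0.37, 0.000106), NRF2 (0.29, 0.000133) and metallothionein lists (0.58, 0.0114) rose. The MHC class II (-0.31, adjusted p = 0.00623), endoplasmic reticulum chaperone (-0.36, 0.0213), cholesterol biosynthesis (-0.44, 0.024) and plasma cell lists (-0.42, 0.0424) fell. With an estimated correlation 0 lists passed, with an adjusted p = 0.491 for 8 of these lists and an adjusted p = 0.592 for cholesterol biosynthesis. That correlation (0.658 for heat shock and 0.578 for mitosis) came from residuals about 1 mean per compound, which hold the dose effect of BNTX. It therefore does not separate a shared dose effect from other shared variation. Without BNTX 10 µM, or without naloxone 2 µM, 5 lists passed. Without BNTX 10 µM the direction of the cholesterol biosynthesis test turned (median 0.08). Over all genes tested, 0 members of these 9 lists passed in the compound fit. Adjusted over the list alone, 14 heat shock, 6 NRF2, 5 ATF4, 1 MHC class II, 1 cholesterol biosynthesis and 1 plasma cell gene passed, and 0 mitosis, metallothionein and endoplasmic reticulum chaperone genes. Among lists that did not pass, CCR7 of the NF-kB list and BCL2 of the apoptosis list passed over all genes. Adjusted over the list alone, 7 glycolysis and hypoxia, 6 immediate early, 2 NF-kB, 2 apoptosis and 2 opioid list genes passed. The interferon, p53, DNA replication, reference and myeloid lists had 1 each, and the proteasome, B cell, Toll-like receptor, ribosomal protein and epithelial and fibroblast lists had 0. The NF-kB list had a median of -0.16, a mean of 0.02 and a test pointing down (adjusted p = 1). The direction of that test flipped under median centring, quantile normalization without background correction, the authors' values and an offset of 50. The type I interferon test (median 1.26e-05, mean 0.13, test up) flipped under the same settings. The Toll-like receptor list (median 0.000141, mean -0.01, test up) and the epithelial and fibroblast list (median 0.16, mean 0.03, test down) also differed in sign. Between naltrindole and naloxone limma's camera called 0 of 24 lists. The ATF4 list alone had an unadjusted p below 0.05 (limma adjusted p = 0.658).

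From 2 to 10 µM of BNTX, 230 genes were 2-fold higher and 207 lower, against 143 and 157 for naloxone and 0 and 5 for naltrindole. By measured values the largest BNTX differences were those of HSPA6, HSPA7, PLCH2, RMRP and HMOX1, though RMRP was not above background at 2 µM (at least 8.08-fold higher at 10 µM). Quantile normalization without background correction gave 91 higher and 53 lower for BNTX, and the authors' values 90 and 52. Median centring gave 436 and 44 for naloxone, where it left a median of all genes of 0.24. In the dose interaction, 212 genes passed in limma, 130 of them higher and 82 lower with the BNTX dose than with the doses of the others. These calls hold no spread between BNTX arrays, since each BNTX dose had 1 array. HSPA6 rose by 4.0 more, HMOX1 by 3.36 more and DDIT3 by 3.11 more. PUS7 (-2.07) and HMGCS1 (-1.67) fell. Over all genes tested, 13 heat shock, 5 ATF4, 5 cholesterol biosynthesis, 2 mitosis, 2 metallothionein, 2 immediate early and 2 NF-kB list genes passed. Adjusted over the list alone, the numbers were 17, 10, 9, 6, 3, 7 and 5. The NRF2, endoplasmic reticulum chaperone, apoptosis, B cell and myeloid lists had 1 each over all genes (4, 4, 1, 1 and 1 adjusted over the list alone). The plasma cell and glycolysis and hypoxia lists had 0 (2 and 1 adjusted over the list alone), and the other lists had 0 by either count. Against naltrindole alone, without the naloxone arrays, 190 of the 212 genes differed by 2-fold or more in the same direction, an alternative chosen after the data were seen. It uses the BNTX and naltrindole arrays that selected the 212 genes and so is no separate test. The number of genes was 105 with median centring (48 higher and 57 lower) and 335 with the mean of a gene's probes. The split was 188 and 63 without background correction and 190 and 64 in the authors' values.

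The BNTX differences at 2 and 10 µM were compared on arrays that share no control. Of 22 genes 2-fold higher with BNTX than with naloxone at 2 µM, 19 were also 2-fold higher with BNTX than with naltrindole at 10 µM, where independent lists would share 0.863. Of 12 lower genes 4 were shared, against 0.41. Across 10506 genes, Pearson's r was 0.442 and Spearman's rho 0.414. With naloxone and naltrindole exchanged, r was 0.378 and rho 0.343. For naloxone at 2 µM minus DMSO against naloxone minus naltrindole at 10 µM, r was 0.112. Of the 5 relations computed, the others were r = -0.0293 (naltrindole at 2 µM minus DMSO against naltrindole at 10 µM minus naloxone at 2 µM) and r = -0.00879 (BNTX minus naltrindole against naloxone minus DMSO at 10 µM). Genes are not independent replicates, so these values describe the arrays and carry no p-value.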

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

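The tests of snoRNA genes, of second probes and of counts about the median of all genes, and the comparison against naltrindole alone, were chosen only after the result was seen.

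The dose difference of BNTX differed from the mean dose difference of naloxone and naltrindole for 212 genes in the test of that difference itself. Of these, 190 differed by 2-fold or more in the same direction against naltrindole alone, on the same BNTX and naltrindole arrays. Of the 135 genes named by rule 41 passed, 26 higher and 15 lower. Among stress genes, log2 values of this difference were 4.0 for HSPA6, 3.48 for ZFAND2A, 3.36 for HMOX1, 3.20 for HSPA7, 3.11 for DDIT3, 3.0 for HSPA4L, 2.90 for BAG3 and 2.72 for DNAJB1. HSPA1B (2.03), PPP1R15A (1.95), ATF3 (1.78), ATF5 (1.31), SLC30A1 (1.62) and MT1X (1.45) were also higher. The same held for PLCH2 (3.37), RMRP (3.31), RNA5S9 (2.93), CEMIP (2.84), BHLHE40 (2.40), LY9 (2.32), DUSP1 (2.14), CTSA (1.69), CENPE (1.48), CENPF (1.43), CD14 (1.29) and HRK (1.28). The single genes that were lower were PUS7 (-2.07), RRS1 (-1.76), RRP12 (-1.73), METTL1 (-1.63), NOP16 (-1.59), GTPBP3 (-1.39), HMGCS1 (-1.67), DHCR7 (-1.57), HSPA5 (-1.40), DLEU1 (-1.96), DDN (-1.84), SPIB (-1.81), NFKB2 (-1.68), PSMG4 (-1.57) and TLCD1 (-1.43). Some of these were not above background on part of the arrays, so their values rest on signals near background and are no exact sizes. RMRP was above background with BNTX at 10 µM alone and CEMIP with BNTX alone. PLCH2 was not above background in DMSO or with naltrindole, HRK in DMSO, with naltrindole or with naloxone at 10 µM, HSPA7 with naloxone at 2 µM, CD14 with naloxone at 10 µM and TLCD1 with BNTX at 10 µM.

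Probes without a gene name lie outside the comparisons above. Of 3736 such probes, 187 differed by 2-fold or more between BNTX at 10 µM and DMSO (103 higher and 84 lower), against 8 of 3677 between naltrindole at 10 µM and DMSO.

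The naloxone 10 µM array stood apart, with 392 genes 2-fold from DMSO against 5 for naltrindole at 10 µM. Scaling of this brighter array needed a count under 40 with median centring, and 722 genes were past 2-fold. The median of all genes was 0.34 with that centring, and 415 genes were counted about that median. Median centring kept the same background correction and moves all genes of an array by the same amount. These counts thus argue only against a constant shift as the whole cause. They do not decide on background or on scaling that varies with brightness. Error of single probes has the value it needs: 2 probes of a gene correlated at r = 0.126 in naloxone minus naltrindole at 10 µM, against 0.745 for BNTX minus naltrindole, but arrays with few differences also gave low values (0.0931 for naltrindole at 10 minus 2 µM and 0.0763 for naloxone minus naltrindole at 2 µM), so a low correlation alone does not mark such error. Of 85 genes with a 2-fold difference and a second probe, the second probe had the same direction in 43 (50.6%, median 0.00619), against 193 of 208 (92.8%) for BNTX. A graded effect of naloxone was to give the genes 2-fold apart at 10 µM a median of 0.2 or more in that direction at 2 µM. The value of 0.0701 fell short of it, although 202 of the 304 genes lay in that direction. As a group, the second probes of the 85 genes above did not share the difference. With 1 array of naloxone at 10 µM, error of single probes, scaling that varies with brightness, a graded effect and a response at that dose alone all stay open.

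Structured RNAs other than snoRNAs and scaRNAs were higher with BNTX at 10 µM than in DMSO, with a median of 1.21 over 23 members, of which 23 were higher and 12 at least 2-fold. The class is none of the fixed lists and was formed by gene name after the data were seen. It holds RNA5S9 and RMRP, which were among the highest genes with BNTX at 10 µM. Together with 12 scaRNAs the median was 0.71 over 35 members, of which 31 were higher and the lowest stood at -0.43. Among them were the ribosomal RNAs RNA5S9 (3.75) and RNA28SN5 (2.26), the splicing RNA RNU6ATAC (3.01), the transcription regulator RN7SK (2.01) and the RNase P component RPPH1 (1.77), while RN7SL1 stood at 0.05. The medians were 0.0135 with BNTX at 2 µM, -0.0204 with naltrindole at 10 µM and 0.13 with naloxone at 10 µM (16 of 23 higher, percentile 89.04 of matched random lists, and 0.49 with median centring, where the median of all genes was 0.34). A lower share of mRNA on the whole array was to raise snoRNA genes too, and the median of 139 of them was -0.199 (47 higher). The snoRNA genes may themselves change with BNTX, so this median does not decide on that share. With median centring in place of quantile normalization the class median was 1.15. In this comparison the median of all genes was -0.0191 in the main setting and -0.00834 with that centring. The class value thus argues only against the quantile step as the whole cause. It does not decide on the background correction, which both settings share. Signal near background is argued against by a median of 1.23 over the 19 members detected on all arrays. The background correction, an effect of BNTX at 10 µM and a difference in the RNA of that sample, of which there was 1, stay open, a lower share of mRNA included. These arrays do not separate them.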

How the results depend on the processing

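The comparison against naltrindole alone was chosen only after the result was seen. Replicate numbers allowed no pairing, since the treatments share no more than 1 of them. The fit with dose as a block, given below, matched arrays across compounds by dose. Changes of list medians of BNTX at 10 µM over the alternatives were set against the SD of medians of random gene sets of the same size. They were smaller than that SD in 138 cases and not in 30, and the median of the B cell list turned to -0.0026 with median centring. List tests kept their side of the threshold in 333 cases, lost it in 21 and turned in 30. Named genes kept their side in 2322 cases, passed in 181 more, no longer passed in 19 and turned in 29. Genes and lists that never passed count as kept. Only the 3 genes called in the main setting (CCR7, BCL2 and HAVCR2) could lose a call, so all 19 losses were theirs. Likewise all 21 losses of list tests fell on the 9 lists that passed in the main setting. The 29 and 30 that turned had an adjusted p above 0.05 under the alternative. Signal over background may limit dim genes, which was not tested by brightness. Without background correction the median SD across arrays over all genes was 0.12, against 0.23 with it, and differences were smaller. The dose interaction could not be fitted without any 1 treated array. For the changes below the cause was not tested, except where size rules count more or fewer genes by construction.

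The numbers of genes past the size rule follow in this order: BNTX 2 µM minus DMSO, BNTX 10 µM minus DMSO, Naloxone 2 µM minus DMSO, Naloxone 10 µM minus DMSO, Naltrindole 2 µM minus DMSO, Naltrindole 10 µM minus DMSO, BNTX 2 µM minus Naloxone 2 µM, BNTX 2 µM minus Naltrindole 2 µM, Naltrindole 2 µM minus Naloxone 2 µM, BNTX 10 µM minus Naloxone 10 µM, BNTX 10 µM minus Naltrindole 10 µM, Naltrindole 10 µM minus Naloxone 10 µM, BNTX 10 µM minus 2 µM, Naloxone 10 µM minus 2 µM and Naltrindole 10 µM minus 2 µM. By the 2-fold rule they were 27, 797, 7, 392, 8, 5, 34, 30, 4, 1325, 771, 304, 437, 300 and 5. With quantile normalization without background correction they were 2, 290, 0, 107, 0, 0, 3, 2, 0, 518, 264, 81, 144, 63 and 0. In the authors' processed values they were 2, 287, 0, 102, 0, 0, 3, 2, 0, 514, 261, 80, 142, 63 and 0. With an offset of 50 they were 5, 462, 1, 202, 0, 1, 10, 8, 0, 809, 426, 153, 228, 135 and 0. With a 1.5-fold rule they were 486, 2625, 204, 1885, 220, 191, 454, 444, 171, 3569, 2513, 1655, 1850, 1612 and 151. With a 4-fold rule they were 1, 69, 0, 3, 0, 0, 2, 2, 0, 124, 65, 1, 27, 1 and 0. With median centring they were 22, 765, 7, 722, 3, 4, 30, 21, 1, 1825, 796, 492, 405, 480 and 4. Over genes detected on all arrays they were 17, 690, 4, 372, 0, 2, 24, 15, 0, 1177, 665, 290, 366, 278 and 0.

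The compound fit called 1 gene for BNTX minus naltrindole with median centring and 1 for BNTX minus both others without a detection filter. With dose as a block it called 2 (BNTX minus naloxone), 2 (BNTX minus naltrindole) and 11 (BNTX minus both). With a slope on dose, which gives the 10 µM arrays the most weight, it called 3135 (BNTX minus naloxone), 1944 (BNTX minus naltrindole), 391 (naltrindole minus naloxone), 2931 (BNTX minus both), 2261 (BNTX minus DMSO) and 1326 (naloxone minus DMSO). With each array left out in turn the counts ranged from 0 to 1019 (BNTX minus naloxone), 0 to 833 (BNTX minus naltrindole), 0 to 1320 (BNTX minus both) and 0 to 396 (BNTX minus DMSO). The highest of each was without BNTX 2 µM, which leaves the lone 10 µM array, assumed to vary like the others. The lists called ranged from 5 (without BNTX 10 µM, and without naloxone 2 µM) to 9, and were 0 with an estimated correlation. The dose interaction called 105 genes with median centring and 335 with the mean of a gene's probes. The correlation of BNTX differences across doses was 0.508 over genes detected on all arrays, 0.519 without background correction and 0.521 in the authors' values. With naloxone and naltrindole exchanged the last 2 were 0.448 and 0.449.

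Values of BNTX minus both others whose direction turned (for lists the median, where the direction is that of the test) were these. With median centring, they were PNOC -0.14, B2M -0.0299, CD3G -0.14, FCGR3A -0.0404, ITGAM -0.11, DCN -0.00272, NF-kB list -0.34, interferon list -0.13 and reference list -0.0727. With the mean of a gene's probes, they were RPL37 -0.0276 and interferon list -0.000876. With a slope on dose, it was ITGAM -0.0319. Without background correction, they were NF-kB list -0.10 and interferon list -0.0104. In the authors' values, they were NF-kB list -0.0935 and interferon list -0.0106. With an offset of 50, they were NF-kB list -0.14 and interferon list -0.00983. Without a detection filter, they were Toll-like receptor list -0.017 and interferon list -0.061. Over genes detected on all arrays, it was interferon list -0.0778. Without members of another list, they were NF-kB list -0.14 and p53 list -0.0112.

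With each array left out in turn, these values of BNTX minus both others spanned 0 or turned the direction of the test: RPTOR from -0.43 to 0.00526, IFIH1 from -0.0152 to 0.58, CD28 from -0.26 to 0.13, ITGAM from -0.28 to 0.34, HMGCS1 from -1.59 to 0.29, HSPA5 from -1.66 to 0.0293, SLC30A1 from -0.0284 to 1.55, XBP1 from -1.17 to 0.0741, CENPE from -0.03 to 1.51, DHCR7 from -1.43 to 0.0435, NSDHL from -1.16 to 0.0851, PNOC from -0.24 to 0.29, CD3G from -0.0179 to 0.0198, DCN from -0.12 to 0.45, FCGR3A from -0.021 to 0.22, ACTA2 from -0.0541 to 0.39, Toll-like receptor list from -0.0237 to 0.0941, interferon list from -0.17 to 0.0879, epithelial and fibroblast list from -0.12 to 0.25, NF-kB list from -0.32 to 0.11, cholesterol biosynthesis list from -0.84 to 0.0805 and B cell list from -0.0767 to 0.10. For HMGCS1, HSPA5, XBP1, DHCR7, NSDHL, SLC30A1, CENPE and the cholesterol biosynthesis list the value that turned was the one without BNTX 10 µM.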

Other observations

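The 2 gene lists here were drawn up after the data were seen, without the genes that prompted them, and the values of SNORD3 genes were also chosen after they were seen.

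Lysosome and autophagy genes were higher with BNTX at 10 µM. Of 33 measured, 21 were at least 2-fold higher than in DMSO (median 1.12) and 0 were 2-fold lower. The membrane protein gene LAMP1 stood at 2.02, the peptidase gene TPP1 at 2.05, and RRAGC and FNIP1, which act in lysosomal nutrient signalling, at 2.41 and 1.96. The hexosaminidase gene HEXA, not above background in DMSO, was at least 2.37-fold higher. With naloxone and naltrindole at 10 µM the median was -0.01 and -0.03. In BNTX minus naltrindole at 10 µM it was 1.18 (percentile 100 of matched random lists), which uses the array that prompted the list and so is no separate test of a shared rise. On the arrays of the lower dose the median was 0.35 in BNTX minus naloxone and 0.28 in BNTX minus naltrindole (percentile 100 for both).

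Ribosome biogenesis genes were lower with BNTX at 10 µM. Of 39 measured, 16 were at least 2-fold lower than in DMSO (median -0.94) and 0 were 2-fold higher. LYAR stood at -1.32 and the helicase gene DDX21 at -1.06, and MYBBP1A, not above background with BNTX at 10 µM, was at least 2.31-fold lower. Against the same DMSO array the median was -0.18 with BNTX at 2 µM (percentile 0 of matched random lists, 31 genes lower), -0.11 and -0.05 with naloxone at 2 and 10 µM (percentiles 0.255 and 38.4, 30 and 20 lower), and -0.05 and -0.10 with naltrindole at 2 and 10 µM (percentiles 5.03 and 0.15, 26 and 34 lower). At 2 µM it was -0.04 in BNTX minus naloxone (percentile 10.02, 22 lower) and -0.11 in BNTX minus naltrindole (percentile 0.52, 30 lower), so the place of the list at this dose depended on the antagonist it was set against. In BNTX minus naltrindole at 10 µM the median was -0.75 (percentile 0), which uses the array that prompted the list and so is no separate test of a shared fall.

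The snoRNA genes of the U3 family, SNORD3A, SNORD3C and SNORD3D, stood at 1.41, 1.29 and 1.43 with BNTX at 10 µM, above the median of -0.20 over 139 snoRNA genes. The 12 scaRNA genes had a median of 0.20.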
